A study of Homo sapiens with 33 samples.

How the data were processed

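RNA was measured in 15 libraries of HepG2 cells, 12 from 6 sorted cell-cycle fractions and 3 from bulk cells. Per the labels' protocols the sorted libraries were made with a low-input stranded total RNA kit and the bulk libraries with a stranded mRNA kit, with more reads planned for the sorted libraries, and the labels name nuclear RNA as the molecule for both. The 18 Repli-seq samples were not analysed here. The submitters' processing notes name cutadapt, Trimmomatic, HISAT2, BWA and SAMtools and the genome build hg38, with no role or version. The program and annotation that gave values per gene are not given in the sources used here.

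The deposited files hold log2 values, 1 value for each of 78932 gene identifiers. These values were log2(TPM + 1), since the back-transformed values summed to 1e+06 in all 15 libraries. The design had been fixed for TPM, and the same tests were kept. Symbols were matched for 61481 identifiers from a table of gene names, and positions come from a RefSeq table of the same genome build.

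TPM keeps no depth, but its steps do. The values of a gene are whole multiples of what 1 read is worth in a library, which gave read counts and gene lengths for 50305 of 50310 genes above 0 in at least 3 libraries, and 99.4% of the lengths found from low values alone were whole within 0.01 base. In data simulated from these counts, 99.2% of 47000 genes had every count recovered exactly. Whether a unit is a read or a read pair is not given in the sources used here. Sorted libraries held 6078955 to 18357521 recovered reads and bulk libraries 22324077 to 24404095. Counting error is only part of the spread.

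Groups and replicate numbers were taken from the labels. The main test was limma with an intensity trend on log2(TPM + 1) in genes with a mean TPM of at least 1, without a term for the replicate, with Benjamini-Hochberg adjustment at 0.05. The 12 sorted libraries shared a fit for any difference among the fractions, G2 against G1, S (mean of S1 to S4) against G1, G2 against S and the slope over S1 to S4. All 15 libraries shared a fit for the mean of the sorted fractions against bulk. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. In data simulated for G2 against G1 over 17022 genes, this test recovered 4% of changes of 1 log2 unit and 56% of changes of 2 log2 units, and called 0.024% of unchanged genes. The changed genes were drawn from well-expressed genes alone, and the simulated noise was independent between libraries. These shares therefore need not hold for the typical gene tested.

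Lists of genes were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, and with an estimated correlation as an alternative. The 17 lists were replication-dependent and replication-independent histones, G1/S genes, G2/M genes, condensation and cohesion, homologous recombination and Fanconi genes, p53 targets, hepatocyte secreted proteins, cholesterol synthesis, glycolysis, unfolded protein response, immediate early and heat shock genes, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, small non-polyadenylated RNAs, nuclear long noncoding RNAs, and markers of fibroblasts, endothelium and leukocytes. Counts are also given adjusted over the list alone. Named genes were a fixed set of cell-cycle, histone, nuclear RNA and liver genes, then per comparison the 6 largest rises and the 6 largest falls among called genes with a mean TPM of at least 5, no overlap between the libraries of both sides and a symbol that is no clone, locus or pseudogene name. In each list described, up to 4 members with the highest means and up to 3 called members with the largest change followed. Genes outside this rule are named as chosen after their values were seen.

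The alternatives fixed before the data were examined changed the pseudocount, the filter, the scaling, the trend, the weights, the replicate term and the libraries. For each comparison among the sorted fractions 12 further fits were added after the data had been seen. They used recovered read counts with limma's voom, protein-coding genes alone, other scalings, weights and filters, with or without a term for the replicate number. The groups share 2 replicate numbers. Any comparison therefore had only 2 same-numbered pairs, although the replicate term was estimated over all 6 sorted fractions. The labels name no shared culture or day. The check of the numbers was computed after the calls of these fits had been seen, so the fit without the replicate term was kept for all main values. A shift shared by libraries of the same number therefore stays in the spread of the main fit, which can hide changes. Genes with near-identical copies, such as those of small nuclear RNAs and histones, are uncertain where reads were divided among copies. No 2 replicates agreed within sampling noise, with chi-square per degree of freedom of at least 2.98. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.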

Results

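The series measured RNA in HepG2 cells, an established human hepatocellular carcinoma line, after the cells had been sorted by their place in the cell cycle. RNA libraries came from 6 sorted fractions, named G1, S1, S2, S3, S4 and G2 in the labels, with 2 libraries each (replicates 2 and 3), and from bulk cells with 3 libraries. Repli-seq, which reads when each stretch of DNA is copied, made up the other 18 of the 33 samples and was not analysed here. The labels give no separate cultures for the replicates, so p-values measure only the spread between these libraries, which may be technical. The read counts recovered from the values came to between 6078955 and 18357521 per sorted library and between 22324077 and 24404095 per bulk library. The deepest sorted library, S4 replicate 3, held 18357521, and no other sorted library held more than 9259092.

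Short noncoding RNA took 75.9% ± 4.89 of the TPM in the sorted libraries (SD, n = 12) and 1.25% ± 0.0302 in bulk (SD, n = 3). Of the recovered reads it held 11.2% ± 1.44 and 0.0800% ± 0.00175, since TPM divides by gene length. Protein-coding genes took 12.6% ± 1.49 of the TPM in the sorted libraries and 77.1% ± 0.433 in bulk, although they held 71.7% ± 3.42 and 93.3% ± 0.109 of the recovered reads. Mitochondrial genes took between 2.22% and 16.7% of the TPM in single sorted libraries and 17.7% ± 0.469 in bulk, but held 8.86% ± 4.88 of the recovered reads in the sorted libraries (2.09% to 15.8%) and 4.61% ± 0.113 in bulk. More genes had a value above 0 in the sorted libraries, 37225 ± 3723 against 22014 ± 198 in bulk.

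**Figure D1:**
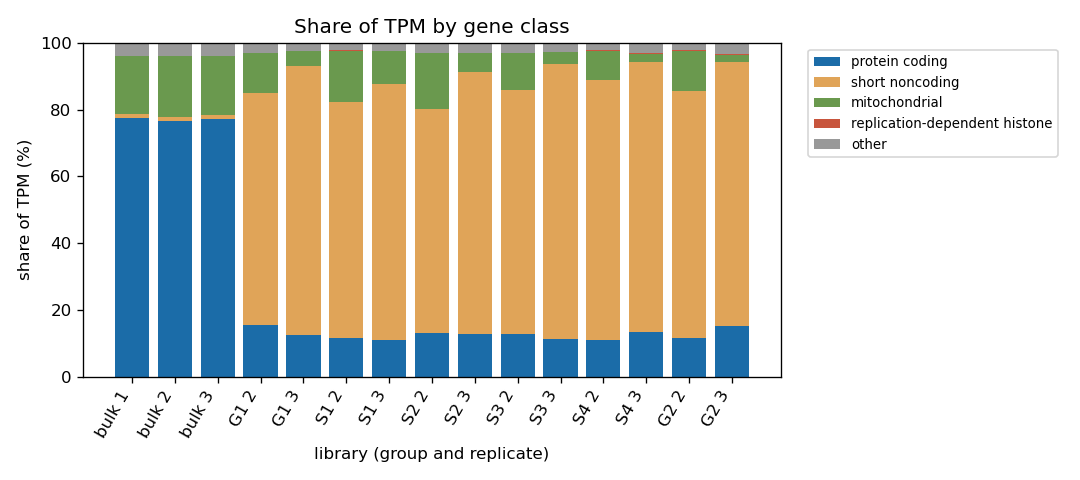
Share of TPM (percent, vertical axis) by gene class in each of the 15 RNA libraries (horizontal axis, group and replicate number), 1 stacked bar per library. Short noncoding RNA takes between 67.2% and 82.5% in the sorted libraries and no more than 1.28% in bulk.

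Across genes, bulk libraries lay closest together, with Pearson correlations of log2(TPM + 1) between 0.988 and 0.989 over 17174 genes. The 2 libraries of a sorted fraction correlated with a median of 0.888, less than libraries of different fractions with the same replicate number, whose median was 0.923. Sorted and bulk libraries correlated with a median of 0.462 over all gene classes and of 0.835 over 13006 protein-coding genes rescaled to 1e+06. These correlations are across genes, which are not independent replicates.

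The comparison of S with G1 addressed which transcripts differ once cells have begun to copy their DNA. Genes of the G2/M list, which act in mitotic entry, spindle assembly and chromosome segregation, had higher values in S, the mean of S1 to S4, than in G1, with a median log2 fold change of 1.15 over 58 members. With limma, without a term for the replicate number, and Benjamini-Hochberg adjustment, 30 of the 58 rose when adjusted over the list alone, none fell, and none passed over all genes tested. AURKB, a mitotic kinase of the chromosomal passenger complex, rose by 2.10 ± 0.43 (SE) on the log2(TPM + 1) scale (limma, adjusted p over the list = 0.0217), from 8.67 ± 5.89 TPM in G1 (SD, n = 2) to between 15.3 and 59.6 TPM in the means of the S fractions. CENPA, the histone H3 variant of centromeres, rose by 1.90 ± 0.46 (limma, adjusted p over the list = 0.0319). CDC25C, a phosphatase that activates CDK1, rose by 1.73 ± 0.34 (limma, adjusted p over the list = 0.0217). PLK1, a mitotic kinase encoded on chromosome 16 from 23678889 to 23690367 (GRCh38), rose by 1.35 ± 0.36 and TOP2A, the DNA topoisomerase that untangles sister chromatids, by 1.14 ± 0.38 (limma, adjusted p over the list = 0.0319 and 0.0366). CCNB1, the mitotic cyclin, rose by 1.28 ± 0.41 (limma, adjusted p over the list = 0.0360). The log2 differences of MKI67 (0.39 ± 0.31), CCNA2 (1.19 ± 0.51), CDK1 (1.60 ± 0.70), AURKA (1.11 ± 0.43) and CDC20 (1.14 ± 0.55) did not pass. AURKB, CENPA and CDC25C were chosen after their values were seen. Without any 1 sorted library the list's median lay between 0.78 and 1.52. In replicate 2 its median log2(TPM + 1) was 2.49 in G1 and 2.74 to 4.47 in the S fractions. In replicate 3 it was 3.36 in G1 and 3.75 to 4.88 in the S fractions. The count of 30, but not the direction, depended on single libraries. It fell most without G1 replicate 2, S1 replicate 3, S2 replicate 3, S3 replicate 2 or S4 replicate 3. The count came to 50 after median-ratio scaling, 48 after quantile normalization and 52 in recovered read counts. With the replicate term, an alternative fixed before the data were examined, the count came to 44, and none passed over all genes.

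Replication-dependent histone genes, which supply histones for new chromatin, had a median log2 difference of 0.43 between S and G1 over 51 measured members, and none passed over all genes or adjusted over the list alone. In recovered read counts 8 of 49 rose when adjusted over the list alone, at a median of 0.66, and none passed over all genes. H4C3 differed by 0.36 ± 0.30 and H1-4 by 0.13 ± 0.41. Genes of the G1/S list, which license and start DNA replication, had a median of -0.19 over 49 members with none called. It was 0.25 without G1 replicate 3, a fit that mixes in the shift between replicate numbers. In replicate 2 the median log2(TPM + 1) of these genes was 3.12 in G1 and 2.64 to 3.36 in the S fractions. In replicate 3 these genes stood at 4.06 in G1 and 3.53 to 4.02 in the S fractions. Among them MCM5, a subunit of the replicative helicase, differed by -1.01 ± 0.35, from 24.3 ± 8.84 TPM in G1 to between 8.39 and 15.6 TPM in the means of the S fractions. RRM2, which makes deoxynucleotides, differed by 0.80 ± 0.40, PCNA by -0.27 ± 0.60, CDC6 by -0.25 ± 0.57, CCNE1 by -0.40 ± 0.48 and CCNE2 by -0.43 ± 0.45. Over all 17022 genes tested with limma, S against G1 gave 0 calls, with 891 genes at an unadjusted p under 0.05, and the median of all genes was -0.20. That median was -0.03 after median-ratio scaling. Of 22 fits of S against G1, 12 of them added after the data had been seen, 8 held the replicate term. Among these 8, 6 called more than 10 genes, up to 357. The 14 fits without the term called at most 4.

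In the list test of limma's camera with a preset correlation, the G2/M list stood above other genes in S against G1 (adjusted p = 7.52e-62), as did the replication-dependent histones (adjusted p = 9.94e-22), the small non-polyadenylated RNAs (median 0.24, adjusted p = 3.17e-05) and the condensation and cohesion genes (median 0.53, adjusted p = 1.81e-07). None of these held with an estimated correlation, where the adjusted p was 0.231, 0.231, 0.231 and 0.544. The estimated correlation between members of the G2/M list was 0.832. It came from a fit without the replicate term, so a shift shared by libraries of the same number enters it. With the term on log2(TPM + 1), no list among the sorted fractions passed with an estimated correlation either. Replication-independent histones (median 0.02, adjusted p = 0.00403), homologous recombination genes (median 0.02, adjusted p = 0.00542) and p53 targets (adjusted p = 0.0216) passed in this fit with the preset correlation only, with adjusted p = 0.544, 0.958 and 0.958 with an estimated correlation. Without G1 replicate 2 the condensation and cohesion genes had a median of -0.03, and neither they nor the small RNAs passed. Homologous recombination genes did not pass without G1 replicate 2, where their median was -0.25, or without S1 replicate 3. The median of the replication-independent histones was -0.05 without S1 replicate 3. The p53 targets had a median of -0.03, a mean of 0.03 and a test upwards, and did not pass without any 1 of 5 libraries, which were G1 replicate 2 and replicate 3 of S1, S2, S3 and S4. Of the replication-independent histones, 1 of 11 rose when adjusted over the list alone, which was CENPA.

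G2 against G1 asked which transcripts differ between the ends of the cycle as sorted. The G2/M list had a median log2 difference of 1.35 over 58 members, and 5 members rose when adjusted over the list alone with limma. These were CENPA (2.35 ± 0.59), AURKB (2.11 ± 0.55), PLK1 (1.91 ± 0.45), CCNB2 (1.79 ± 0.40) and CDC25C (1.67 ± 0.44), each with an adjusted p over the list of 0.0413, and all but PLK1 were chosen after their values were seen. PLK1 stood at 9.75 ± 0.620 TPM in G1 and 44.1 ± 28.2 TPM in G2 (SD, n = 2 each). CCNB1 stood at 12.2 ± 2.56 TPM in G1 and 51.3 ± 33.6 TPM in G2, a log2 difference of 1.83 ± 0.51 that did not pass. The log2 differences of CDK1 (1.82 ± 0.88), CDC20 (1.65 ± 0.69), AURKA (1.55 ± 0.54), CCNA2 (1.45 ± 0.64), TOP2A (1.30 ± 0.48) and MKI67 (0.30 ± 0.40) did not pass either. The count of 5 came to 39 after median-ratio scaling, to 38 after quantile normalization, to 37 after rescaling without mitochondrial, short noncoding and histone genes, to 42 in recovered read counts, to 8 with a pseudocount of 0.1 or a mean TPM of at least 5, to 0 with array weights or without the trend, and to 47 without G2 replicate 2. It came to 0 without any 1 of 8 libraries, which were G1 replicate 2, G2 replicate 3 and both libraries of S2, S3 and S4, and the list's median was 0.63 without G2 replicate 3. With the replicate term, an alternative fixed before the data were examined, 45 of the 58 members rose when adjusted over the list alone and none over all genes. G1/S genes had a median of -0.14 with none called, and of 0.34 without G1 replicate 3 and 0.42 without G2 replicate 2. The latter 2 fits mix in the shift between replicate numbers. The list's median log2(TPM + 1) in G1 and G2 was 3.12 and 2.86 in replicate 2, and 4.064 and 4.057 in replicate 3. MCM5 differed by -0.22 ± 0.45 and PCNA by -0.26 ± 0.76. In the condensation and cohesion list 1 of 21 members rose when adjusted over the list alone, PTTG1, the securin that inhibits separase until anaphase. PTTG1 rose 2.83-fold with an SE of 0.36 on the log2 scale (limma, adjusted p over the list = 0.0404), and it was chosen after its values were seen. Over all genes limma called 1 gene, higher in G2, an unnamed short noncoding RNA of 102 bases (ENSG00000206824) that was chosen after its values were seen, with 469 genes at an unadjusted p under 0.05. The count was 2 without S2 replicate 2 or G2 replicate 2, and 0 without any other of the 12 sorted libraries. A fit on the G1 and G2 libraries alone called 106, with 51 higher and 55 lower in G2. Of 22 fits on all sorted libraries, 12 of them added after the data had been seen, 8 held the replicate term. Among these 8, 5 called more than 10 genes, up to 97. The 14 fits without the term called at most 1.

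With the preset correlation, camera placed the G2/M list (adjusted p = 3.40e-57), replication-dependent histones (median 0.30, adjusted p = 5.72e-10), condensation and cohesion genes (median 0.36, adjusted p = 1.31e-05), small non-polyadenylated RNAs (median 0.31, adjusted p = 0.00200) and replication-independent histones (median 0.03, adjusted p = 0.0382) above other genes in G2 against G1. With an estimated correlation the adjusted p was 0.428, 0.750, 0.795, 0.580 and 0.795. The median of the replication-dependent histones was -0.02 without G2 replicate 3. The condensation and cohesion genes had medians of -0.09 without G1 replicate 2 and -0.17 without G2 replicate 3, and passed in neither. The small RNAs did not pass without G1 replicate 2 or G2 replicate 2. The replication-independent histones did not pass without any 1 of 5 libraries, and their median was -0.14 without G2 replicate 3. Both comparisons used the same G1 libraries, so their chance values are shared.

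**Figure D2:**
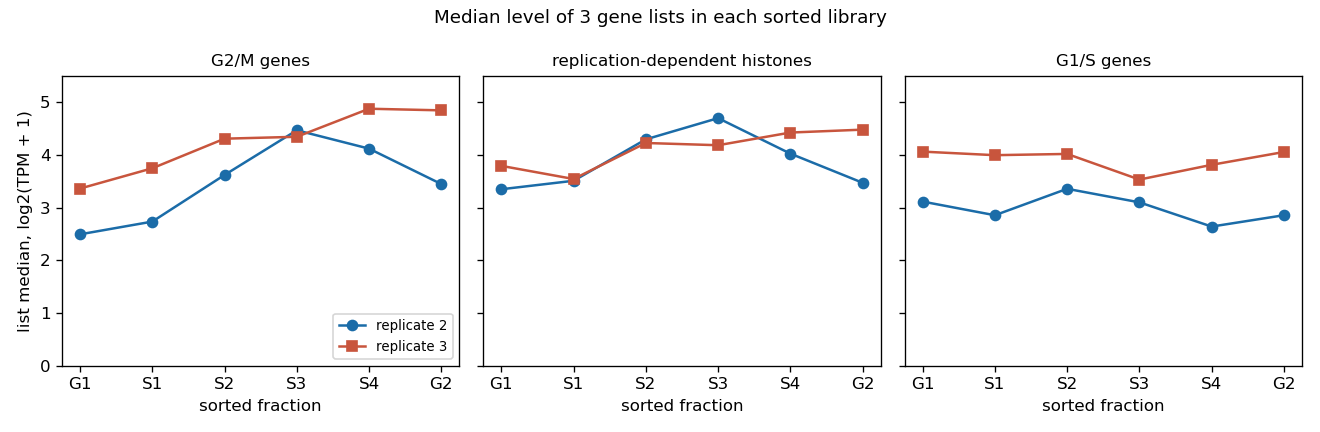
Median log2(TPM + 1) of the G2/M genes, the replication-dependent histones and the G1/S genes (vertical axis) in each of the 12 sorted libraries, by fraction (horizontal axis), with 1 line per replicate number. The G2/M median is lowest in G1, at 2.49 in replicate 2 and 3.36 in replicate 3, and lower in G2 than in S4 in both, at 3.45 against 4.12 in replicate 2 and 4.85 against 4.88 in replicate 3.

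From S1 to S4 the G2/M list had a median slope of 0.42 log2 units per fraction, and 21 of 58 members rose when adjusted over the list alone with limma. CENPA, chosen after its values were seen, had the steepest of the named slopes, 0.91 ± 0.19, then PLK1 with 0.73 ± 0.14 and CCNB1 with 0.70 ± 0.16 (limma, adjusted p over the list = 0.0170, 0.0170 and 0.0199). CDC20 (0.64 ± 0.22), CCNB2 (0.57 ± 0.13, chosen after its values were seen), TOP2A (0.55 ± 0.15), AURKB (0.55 ± 0.17), AURKA (0.53 ± 0.17) and TPX2 (0.51 ± 0.16) also rose, adjusted over the list alone. PLK1 means went from 10.4 ± 3.84 TPM in S1 to 49.2 ± 14.3 TPM in S4 (SD, n = 2 each). CDK1 (0.43 ± 0.28), CCNA2 (0.41 ± 0.20), MKI67 (0.27 ± 0.13) and CDC25C (0.38 ± 0.14) did not pass. PTTG1 had a slope of 0.51 ± 0.11, the only member of 21 in the condensation and cohesion list that rose when adjusted over the list alone (limma, adjusted p over the list = 0.0263). The median slope of the G2/M list was 0.28 without S1 replicate 2. The count of 21 came to 0 without S1 replicate 2 or S4 replicate 3, to 40 without S1 replicate 3 and to 37 without G2 replicate 2 or G2 replicate 3, and lay between 7 and 9 without S2 replicate 2, S3 replicate 2, S3 replicate 3 or S4 replicate 2. It also came to 42 in recovered read counts, to 37 with array weights, to 34 after rescaling without mitochondrial, short noncoding and histone genes, to 32 after median-ratio scaling or quantile normalization, to 11 with a pseudocount of 0.1, to 9 without a filter and to 8 without the trend. With the replicate term, fixed as an alternative before the data were examined, the count came to 51, and none passed over all genes. G1/S genes had a median slope of -0.09 with none called, and CCNE1 and CCNE2, the cyclins of S-phase entry, had slopes of -0.42 ± 0.19 and -0.38 ± 0.18. Hepatocyte secreted proteins had a median slope of -0.19 and mitochondrially encoded mRNAs one of -0.47, with no member called in either. The hepatocyte slope was -0.10 without S1 replicate 2 and -0.08 without S4 replicate 3. Mitochondrially encoded mRNAs were lower in replicate 3 than in replicate 2 in all 6 fractions, by a median log2 difference of -1.77, and their slope was -0.22 without S4 replicate 3 and -0.74 without S4 replicate 2. Over all genes limma called 0 for the slope, with 500 at an unadjusted p under 0.05. Of 22 fits of the slope, 12 of them added after the data had been seen, 8 held the replicate term. Among these 8, 6 called more than 10 genes, up to 823. The 14 fits without the term called at most 1.

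The preset camera test placed the G2/M genes (adjusted p = 1.42e-39), replication-dependent histones (median 0.15, adjusted p = 7.00e-08), replication-independent histones (adjusted p = 0.00258), condensation and cohesion genes (adjusted p = 0.00682) and ribosomal proteins (median 0.07, adjusted p = 0.000180) above other genes along S1 to S4. It placed G1/S genes (adjusted p = 1.06e-07), hepatocyte secreted proteins (adjusted p = 2.64e-10), mitochondrially encoded mRNAs (adjusted p = 2.98e-10), cholesterol synthesis genes (median -0.02, adjusted p = 0.0336) and unfolded protein response genes (median -0.01, adjusted p = 0.0453) below. None held with an estimated correlation, where adjusted p values ran from 0.535 to 0.732. G1/S genes had median slopes of 0.03 without S1 replicate 3 and 0.04 without S4 replicate 2, and passed in neither. Condensation and cohesion genes did not pass without S1 replicate 2 or S4 replicate 3, replication-independent histones without S1 replicate 2, or ribosomal proteins without S1 replicate 3. Cholesterol synthesis and unfolded protein response genes did not pass without any 1 of 5 and any 1 of 7 libraries.

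The comparison of G2 with S addressed which transcripts differ after DNA copying has ended. The G2/M genes had a median log2 difference of 0.15 between G2 and S with none called, which was 0.80 without G2 replicate 2 and -0.50 without G2 replicate 3. The differences of PLK1 (0.56 ± 0.36), CCNB1 (0.56 ± 0.41) and TOP2A (0.16 ± 0.38) did not pass. MCM5 differed by 0.79 ± 0.35, which did not pass. Mitochondrially encoded mRNAs had a median of -0.59 and camera with the preset correlation placed them below other genes (adjusted p = 1.44e-05), and replication-dependent histones too (median -0.07, adjusted p = 0.000544), both with adjusted p = 0.973 with an estimated correlation. The mitochondrial median was 0.64 without G2 replicate 3, where that list stood above other genes (adjusted p = 0.000586), and the histone median was 0.29 without G2 replicate 2, where that list did not pass. Over all genes limma called 1, RNU6-106P, named as a pseudogene copy of the U6 spliceosomal RNA and chosen here after its values were seen, with 289 genes at an unadjusted p under 0.05. That count was 2 without either S2 library and 0 without any other sorted library. The test of any difference among the 6 fractions called 3 genes of 17022, RNU6-106P, RNU7-181P and the unnamed RNA of 102 bases, with 470 at an unadjusted p under 0.05. All 3 were chosen after their values were seen, and the count was 2 without S2 replicate 2 or G2 replicate 2, 1 without S2 replicate 3 and 0 without any other sorted library. Their lowest group mean was 0 TPM and their highest lay between 8.34 and 14.3 TPM. Of 22 fits for any difference, 12 of them added after the data had been seen, 8 held the replicate term. Among these 8, 5 called more than 10 genes, up to 727. The 14 fits without the term called at most 4. Glycolysis, immediate early and heat shock genes and nuclear long noncoding RNAs passed no list test among the sorted fractions in the fit on log2(TPM + 1) without a replicate term.

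Sorted libraries were made with a total RNA kit and bulk libraries with an mRNA kit. The 2 groups also differed in input and sorting, so kit, input and sorting cannot be told apart here. Small nuclear RNAs that carry no poly(A) tail were abundant in the sorted libraries, with all 14 measured members of the list of small non-polyadenylated RNAs higher than in bulk at a median log2 difference of 10.32, which depends on the pseudocount of 1 TPM where bulk is at 0. RNU4-2, the U4 RNA of the spliceosome, had group means between 20044 and 25325 TPM in the sorted fractions and was listed at 0 in bulk, as were RNU5A-1, RNU6-7 and the 5S ribosomal RNA gene RNA5S9. That list passed camera with an estimated correlation too (adjusted p = 0.0152). Of 50 replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, 47 were higher and 2 lower, at a median of 3.34, with adjusted p = 0.184 with an estimated correlation. H1-4 was higher by 7.27 ± 0.30, H3C2 by 6.05 ± 0.39, H4C3 by 5.48 ± 0.23 and H2AC20 by 4.22 ± 0.27 on the log2 scale. H4C3 stood at 0.149 ± 0.257 TPM in bulk (SD, n = 3) and at 41.0 ± 1.97 TPM in G1 (SD, n = 2). The nuclear-retained RNAs MALAT1, at 26.2 ± 2.45 TPM in bulk and 1865 ± 694 TPM in G1, and NEAT1 were higher by 6.32 ± 0.43 and 2.47 ± 0.50. Of the 13 measured nuclear long noncoding RNAs, 7 were higher and 3 lower. That list passed camera with the preset correlation (adjusted p = 0.0114) but not with an estimated one (adjusted p = 0.472).

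Ribosomal protein genes had 70 of 72 measured members lower and 1 higher, at a median of -4.42 (preset camera, adjusted p = 3.11e-14, and adjusted p = 0.472 with an estimated correlation), with RPS12 at -5.46 ± 0.16, RPLP0 at -5.20 ± 0.18 and RPL7 at -5.95 ± 0.13. EEF1A1, the elongation factor that brings tRNA to the ribosome, fell from 5805 ± 44.0 TPM in bulk to group means between 56.9 and 65.8 TPM. PLA2G2A (-8.67 ± 0.18), S100A4 (-7.85 ± 0.21), PLP2 (-7.16 ± 0.17), CD24 (-6.66 ± 0.18) and MFNG (-6.30 ± 0.21) had the other largest falls. GAPDH, a glycolytic enzyme, differed by -4.99 ± 0.25 and the histone variant gene H3-3B by -3.98 ± 0.26. The plasma protein genes ALB and APOA1 differed by -2.39 ± 0.42 and -1.84 ± 0.30, but by 0.02 and 0.57, neither called, after rescaling without mitochondrial, short noncoding and histone genes. FOS differed by -0.76 ± 0.82, which did not pass. RN7SK and RMRP were listed at 0 in the libraries, and HSPA1A lay below the filter.

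Limma called 13896 of 17174 genes between sorted and bulk libraries, 3966 higher and 9930 lower, or 28.5% higher. That split moved with the scaling, since 54.9% of the calls were higher after median-ratio scaling, 38.8% after quantile normalization and 82.2% after rescaling without mitochondrial, short noncoding and histone genes. The median of all genes was -0.99 as deposited, 0.29 after median-ratio scaling and 1.02 after that rescaling. Ribosomal protein genes stayed lower after it, at a median of -2.03, while G2/M genes went from -2.20 to 0.08 and G1/S genes from -1.79 to 0.56. Of the other lists, as deposited, the medians were -2.26 for replication-independent histones, -1.64 for condensation and cohesion, -0.49 for homologous recombination, -1.95 for p53 targets, -2.29 for hepatocyte secreted proteins, -1.21 for cholesterol synthesis, -3.17 for glycolysis, -2.12 for the unfolded protein response, -2.39 for immediate early and heat shock genes, -3.08 for mitochondrially encoded mRNAs and 1.01 for nuclear long noncoding RNAs. After that rescaling 6 of these medians lay above 0 in place of below, at 0.72 for condensation and cohesion, 1.80 for homologous recombination, 0.38 for p53 targets, 0.11 for hepatocyte secreted proteins, 1.16 for cholesterol synthesis and 0.25 for the unfolded protein response. Of these 6, only homologous recombination and cholesterol synthesis lay above the median of all genes, 1.02 after it. The others stayed below the typical gene, as did G2/M and G1/S genes. Of the markers of fibroblasts, endothelium and leukocytes, 4 of 22 passed the filter as deposited, all lower in the sorted libraries. After that rescaling 8 passed the filter, with 3 higher, 1 lower and a median of 0.77.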

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

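The fits on recovered read counts, the fits on protein-coding genes and the fits that join the replicate term with another scaling were chosen after seeing the data. The replicate term, tried as fixed before the data were examined, gave 3 calls for any difference among the 6 sorted fractions, 1 for G2 against G1, 0 for S against G1, 1 for G2 against S, 0 for the slope over S1 to S4 and 13619 for the sorted fractions against bulk. The differences between replicates 3 and 2 correlated between fractions with a median of 0.323 over 15 pairs of fractions (0.308 to 0.379). Among the libraries of other fractions, 12 of 12 libraries correlated best with one of their own number. Libraries of the same number were thus alike across fractions, for a reason that the labels do not give. In data simulated with a shift between the replicate numbers, the replicate term gave 26% and 83% for changes of 1 and 2 log2 units and 0.03% of unchanged genes. Recovered read counts gave 33%, 99% and 0.047% with the term and 0%, 23% and 0% without it. The count fits shared a simulated set with an assumed spread. Each log2 fit had a set of its own, so the shares of the log2 fits cannot be compared directly. The changed genes were well expressed in every set. Where a cause is not named below, the cause was not tested.

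With the replicate term on log2(TPM + 1) and adjusted over the list alone, 45 of 58 G2/M genes rose in G2 against G1, 44 in S against G1, 51 along S1 to S4 and 0 in G2 against S. Of condensation and cohesion genes 2 rose in G2 against G1 and 10 in S against G1. In S against G1 3 replication-dependent histones and 1 small RNA rose and 4 G1/S genes fell. Along S1 to S4 3 replication-dependent histones rose, and 14 of 24 hepatocyte secreted proteins and 13 of 13 mitochondrially encoded mRNAs fell. None of these members passed over all genes. The preset camera test with the term also passed hepatocyte secreted proteins in G2 against G1 (adjusted p = 6.08e-06), S against G1 (0.00993) and G2 against S (0.0208), mitochondrially encoded mRNAs (4.21e-08), homologous recombination genes (0.0301) and p53 targets (0.0301) in G2 against G1, and ribosomal proteins in G2 against S (0.0208). In this fit none passed among the sorted fractions with an estimated correlation, where the lowest adjusted p was 0.0623.

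In recovered read counts with the replicate term, p53 targets in S against G1 passed camera with an estimated correlation too (adjusted p = 0.0364), with 7 of 28 higher when adjusted over the list alone and 5 over all genes. There 29 of 49 replication-dependent histones rose over the list alone and 8 over all genes, and immediate early and heat shock genes passed with the preset correlation (adjusted p = 0.0251). Without the term, adjusted over the list alone, recovered read counts called 42 G2/M genes in G2 against G1, 52 in S against G1 and 42 in the slope, and in S against G1 also 8 replication-dependent and 3 replication-independent histones, 3 condensation and cohesion genes and 2 small RNAs. No list passed there among the sorted fractions with an estimated correlation. Without the term the preset test also passed hepatocyte secreted proteins (adjusted p = 0.0434), ribosomal proteins (0.0262) and mitochondrially encoded mRNAs (0.0434) in G2 against G1.

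For any difference among the 6 sorted fractions, limma called 0 genes with a mean TPM of at least 5, after rescaling without mitochondrial, short noncoding and histone genes, in protein-coding genes (as such, with array weights or with a mean TPM of at least 10), in recovered read counts and in those of protein-coding genes, and 0 after that rescaling with the replicate term. With the replicate term it called 654 in recovered read counts, 727 in those of protein-coding genes, 168 in protein-coding genes, 184 there with array weights, 208 there with a mean TPM of at least 10, and 5 after median-ratio scaling. Without single libraries the counts lay between 0 and 2, and between 402 and 673 in recovered read counts with the replicate term.

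For G2 against G1 it called 0 without a filter, with a mean TPM of at least 5, after the rescaling, with array weights, in protein-coding genes (as such, with array weights or with a mean TPM of at least 10), in recovered read counts and in those of protein-coding genes. With the replicate term it called 97 in recovered read counts, 90 in those of protein-coding genes, 37 in protein-coding genes, 51 there with array weights and 69 there with a mean TPM of at least 10. A fit on the G1 and G2 libraries alone called 106, with 51 higher and 55 lower. Without single libraries the counts lay between 0 and 2, and between 31 and 124 in recovered read counts with the replicate term.

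For S against G1 it called 4 with a pseudocount of 0.1, 3 without a filter, 2 after median-ratio scaling, 2 after quantile normalization, 1 without the trend, 2 for S1 against G1 and 1 for S4 against G1. With the replicate term it called 357 in recovered read counts, 337 in those of protein-coding genes, 176 in protein-coding genes, 164 there with array weights, 207 there with a mean TPM of at least 10, 41 after the rescaling and 6 after median-ratio scaling. Without single libraries the counts lay between 0 and 2, and between 78 and 375 in recovered read counts with the replicate term.

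For G2 against S it called 2 with a pseudocount of 0.1, 28 without a filter, 2 after median-ratio scaling and 2 after quantile normalization. It called 0 with a mean TPM of at least 5, after the rescaling, with array weights, for G2 minus S4, in the fits on recovered read counts with and without the replicate term, in those of protein-coding genes without it, in the protein-coding fits with and without it, and after the rescaling or median-ratio scaling with it. Recovered read counts of protein-coding genes with the term gave 1, and G2 minus S4 in recovered read counts with it gave 2. Without single libraries the counts lay between 0 and 2, and between 0 and 19 in recovered read counts with the replicate term.

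For the slope over S1 to S4 it called 1 with a pseudocount of 0.1. With the replicate term it called 732 in recovered read counts, 823 in those of protein-coding genes, 252 in protein-coding genes, 604 there with array weights, 414 there with a mean TPM of at least 10 and 24 after the rescaling. Without single libraries the counts were 0, and lay between 125 and 856 in recovered read counts with the replicate term. For the sorted fractions against bulk a mean TPM of at least 5 gave 8947 calls, since fewer genes were tested, and the counts without single libraries lay between 12865 and 14029.

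Without single libraries the list G1/S genes had medians from -0.68 to 0.42 in G2 against G1, from -0.43 to 0.68 in G2 against S from -0.68 to 0.25 in S against G1 and from -0.23 to 0.036 in the slope. G2/M genes had medians from 0.63 to 1.98 in G2 against G1 and from 0.78 to 1.52 in S against G1. In G2 against S they ran from -0.50 to 0.80. Chromosome condensation and cohesion had medians from -0.51 to 0.59 in G2 against S, from -0.17 to 1.10 in G2 against G1 and from -0.025 to 0.67 in S against G1. Replication-dependent histones had medians from -0.016 to 0.77 in G2 against G1 and from -0.46 to 0.29 in G2 against S, and replication-independent histones from -0.14 to 0.37 in G2 against G1 and from -0.054 to 0.13 in S against G1. Median slopes lay from -0.084 to 0.034 for cholesterol synthesis, from -0.046 to 0.0087 for the unfolded protein response, from -0.26 to -0.081 for hepatocyte secreted proteins, from -0.74 to -0.22 for mitochondrially encoded mRNAs, from 0.013 to 0.21 for condensation and cohesion, from 0.090 to 0.22 for replication-dependent and 0.033 to 0.15 for replication-independent histones, and from 0.28 to 0.56 for G2/M genes. Small RNAs had medians from 0.14 to 0.36 in G2 against G1 and from 0.022 to 0.32 in S against G1. Glycolysis had medians from -0.57 to 0.42 in G2 against G1, from -0.10 to 0.35 in G2 against S, from -0.68 to 0.30 in S against G1 and from -0.10 to 0.17 in the slope. Hepatocyte secreted proteins had medians from -0.72 to 0.17 in G2 against G1 and from -0.32 to 0.30 in G2 against S. Homologous recombination and Fanconi genes had medians from -0.25 to 0.43 in S against G1 and from -0.094 to 0.14 in the slope. Mitochondrially encoded mRNAs had medians from -1.90 to 0.57 in G2 against G1 and from -1.84 to 0.64 in G2 against S. The p53 targets had medians from -0.26 to 0.13 in S against G1. In fits without a replicate term such ranges also hold the shift between the replicate numbers.

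Preset camera tests that passed did not pass without a filter for small RNAs and replication-independent histones in G2 against G1 and S against G1, for homologous recombination genes and p53 targets in S against G1, for replication-dependent histones in G2 against S, and for cholesterol synthesis and the unfolded protein response in the slope. After the rescaling this held for replication-independent histones in G2 against G1 and for homologous recombination genes and p53 targets in S against G1, and after quantile normalization for small RNAs in G2 against G1 and the unfolded protein response in the slope. Other directions turned with the scaling or the filter. The median of cytosolic ribosomal proteins in S against G1 was 0.070 in recovered read counts with the replicate term, 0.085 in those of protein-coding genes with it and 0.081 without it, 0.044 in protein-coding genes with it and there with array weights, 0.043 with a mean TPM of at least 10 with and without it, and 0.054 after median-ratio scaling with it. Without a filter the camera test turned for p53 targets in S against G1 (median -0.034) and for homologous recombination and Fanconi genes against bulk (median -0.49). Quantile normalization gave -0.21 for G1/S genes against bulk, where the test turned, and 0.72 for cholesterol synthesis against bulk, which was 1.16 after the rescaling and 1.37 in protein-coding genes. ALB against bulk was 0.021 after the rescaling and 0.23 in protein-coding genes, and APOA1 was 0.57 and 0.78.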

Other observations

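Tests of the splits of the libraries, of depth behind the olfactory receptor reads and of depth behind the mitochondrial difference were chosen after the result was seen. So were the fits on recovered read counts described next.

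Recovered read counts with a term for the replicate number called many G2/M genes, and are given as values because the labels do not pair the libraries. For each comparison among the sorted fractions 22 fits on all 12 sorted libraries were tried, 8 with the replicate term and 14 without, 12 of them added after seeing the data. Their calls ran from 0 to 97 for G2 against G1, from 0 to 357 for S against G1, from 0 to 28 for G2 against S, from 0 to 823 for the slope and from 0 to 727 for any difference. Those without the replicate term called at most 1, 4, 28, 1 and 4. A further fit without the term, on the G1 and G2 libraries alone, called 106 for G2 against G1. In the count fit with the term, 41 of 58 G2/M genes rose in G2 against G1, 51 in S against G1 and 47 along S1 to S4. Genes named from it were chosen after their values were seen. PIF1, a DNA helicase, rose by 3.77 ± 0.48 in G2 against G1 (limma, adjusted p = 0.000392) and KIF20A, a mitotic kinesin, by 2.60 ± 0.37. MCM5 fell by 0.88 ± 0.11 in S against G1 (limma, adjusted p = 0.000212), and FAM111B fell by 0.73 ± 0.09 per fraction along S1 to S4. Without the term and on log2(TPM + 1), PIF1 differed by 3.28 ± 0.59 and MCM5 by -1.01 ± 0.35, and neither passed. Without single libraries this fit called 31 to 124 genes for G2 against G1, 78 to 375 for S against G1 and 125 to 856 for the slope. A fit of protein-coding genes on the log2 scale with the term shared 35 of its 37 calls for G2 against G1 with the count fit, 159 of 176 for S against G1 and 223 of 252 for the slope.

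Of 100 splits of the 15 libraries into 12 and 3, drawn from 455, only 1 gave as many calls as sorted against bulk, which was the real split with 13969 calls in the fit of 12 against 3. The highest other split gave 8176. Since the groups differed in library kit and input as well as sorting, the real split was bound to call many genes. This test therefore cannot decide on chance. Library kit and input differ with the groups and stay open.

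Olfactory receptor genes held 120 to 697 recovered reads in the sorted libraries and 39 to 53 in bulk. Depth is argued against, since the sorted libraries had a median depth of 0.351 of that of bulk. Genomic DNA in the sorted libraries cannot be told apart from other sources. Taste receptor genes held 21.1 times the reads per kilobase of olfactory receptor genes, over the bound set before the result was seen, and more than 4 times in 12 of 12 libraries. Keratin-associated protein genes held 2.24 times, and were more than 4 times apart in 2 of 12 libraries. Lengths were known for only 143 of 380 olfactory, 11 of 24 taste receptor and 8 of 94 keratin-associated protein genes, so that test was void. Taste receptor genes also stood above olfactory receptor genes in bulk, at 1.72 to 3.09 against 0.0789 to 0.107 reads per kilobase, so reads of their own do not exclude genomic DNA in olfactory receptor genes. If the olfactory receptor reads fell evenly on all 380 genes, as genomic DNA would, more genes should be above 0 than were. The median ratio of genes above 0 to those expected was 0.470 (0.352 to 0.578), and under 0.5 in 7 of 12 libraries where at least 9 had been set as the bound. Genomic DNA as the source of most of these reads therefore stays open. No biological explanation was tested.

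Mitochondrially encoded mRNAs were lower in replicate 3 than in replicate 2 in 6 of 6 fractions, by log2 differences from -2.37 to -0.90. Depth as the whole cause is argued against, since in 2 of these fractions, S2 and G2, replicate 3 had fewer reads. G1/S genes were higher in replicate 3 in 6 of 6 fractions, by 0.38 to 1.24. This was not particular to them, since G2/M genes were higher in replicate 3 in 5 of 6 fractions. Their median log2 difference was 0.81 (-0.12 to 1.40). For the G1/S genes, the gene classes that take most of the TPM are argued against as the cause. The median difference of the G1/S genes was 0.96 after rescaling without those classes, and above 0 in 6 of 6 fractions. No day, culture or sort is given in the labels, so a difference between the replicates in growth or handling stays open as untested.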
